A study of Rattus norvegicus with 12 samples.

How the data were processed

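RNA of rat striatum was hybridised to 12 Agilent single-colour (Cy3) expression arrays with 62976 spots each, of which 4259 were controls and the rest held 30367 distinct probes. The labels give 3 numbered arrays per group; whether the non-lesioned and lesioned saline arrays come from the same animals is not stated. The scanner files were made by the authors with Agilent Feature Extraction (10.7.3.1 per the file headers). Their processed signal is an intensity that, per the file headers, had its background subtracted and was detrended within the array but was not scaled between arrays. The authors' combined table of deposited intensity values held the same numbers on all 62976 spots of each array, within a relative tolerance of 1e-06. The median pixel brightness of each spot and of its surroundings is an intensity without background subtraction, per the file headers, and was used in 1 alternative only.

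Spots marked as outliers in the files were left out and spots of a probe were averaged. Log2 processed signals were scaled by subtracting each array's 75th percentile. A probe was tested if it was well above background, by the files' own mark on at least 0.5 of its spots, on all 3 arrays of at least 1 group, which left 21469 probes. Symbols came from a table of RefSeq accessions; 17328 probes matched 1 symbol and 13039 none. Of several probes of a gene, the one with the highest mean signal stood for it, and probes without a symbol were kept, giving 19412 features (11110 with a symbol, 8302 without). Fosb was not matched and is not analysed here. The probe design was built on an older rat assembly than the symbol table, so no coordinates are given.

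One model was fitted with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8) to all 12 arrays with the 4 groups, leaving 8 residual degrees of freedom. Contrasts were lesioned minus non-lesioned saline, L-DOPA minus lesioned saline, L-DOPA with zonisamide minus L-DOPA, and L-DOPA with zonisamide minus lesioned saline. P values were adjusted by Benjamini-Hochberg over the 19412 features of each contrast, with a threshold of 0.05. The tests are two-sided. Errors of the log2 changes of single features are limma's moderated standard errors. In the closing observations, intervals of medians over genes and errors of clock gene means are taken over genes. They leave out the spread between arrays. With 3 arrays per group an exact permutation test cannot go below p = 0.1, so none is given. A group with no array above background gives a fold only as a lower bound, with each dim array's value raised to the lowest signal that array marked as well above background.

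For 27 gene lists covering cell types, neuronal activity, transmitters, stress and the known targets of the drugs, limma's camera was run with a preset correlation of 0.01, adjusted over the lists of a comparison. It was repeated with a correlation estimated per list and with fry. The lists, contrasts, filters and the rule for naming genes were fixed before the data were examined. The rule names, for each comparison, the 8 largest rises and the 8 largest falls among features with a symbol that passed and whose groups did not overlap, or, where fewer than 10 passed, the 10 with the smallest p. It adds the 2 to 4 members with the smallest p of each list spoken of, the genes Pdyn, Drd1, Drd2, Penk, Tac1 and Th in every comparison, and in the zonisamide comparison the genes named for L-DOPA. Some genes that the rule names are not reported. Called genes named in the closing observations, among them those of MHC class I, lie outside this rule and were chosen after their values were seen. Of the 3 calls with camera for the lesion, 9 for L-DOPA, 8 for zonisamide and 6 for both drugs, 1 held with an estimated correlation.

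The arrays came from 5 slides. The first held replicate 1 of all 4 groups, another held replicate 2 of the 3 lesioned groups, and another held replicate 3 of both drug groups with replicate 2 of the non-lesioned side. Replicate 3 of the non-lesioned side and replicate 3 of lesioned saline each lay alone on a slide. In the zonisamide comparison equal numbers shared a slide, and the deviations of same-numbered arrays from their group means correlated at 0.37, 0.19 and 0.25, so there the numbers pair the arrays; in the others they do not. The correlation within slides over all features was 0.11.

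Alternatives tried were quantile normalization, normexp background correction (offset 50) of the median spot brightness followed by quantile normalization (called normexp below), no filter on dim probes, a filter on all 12 arrays, the mean of a gene's probes, only the groups compared, an intensity trend with a robust prior, array weights, the replicate number as a block, slide as a fixed block, and leaving out each array in turn. Slide as a random block, Ttr as a covariate and leaving out the 5 arrays with a replicate-spot spread over 20% were added after the data were seen. Quantile normalization moved the median of all features by -0.138 for the lesion and 0.121 for both drugs, and normexp by -0.127 and 0.116; for the other contrasts the shifts were at most 0.0686. No called list changed the direction of its median under these scalings, but several medians shrank with normexp. That of immediate-early genes went from -0.511 to -0.194 for zonisamide and from -0.579 to -0.239 for both drugs. The blood cell median for zonisamide went from -1.18 to -0.519, and the glucocorticoid-responsive median for both drugs from -0.413 to -0.0593. Others grew, such as the clock median for both drugs, from 0.19 to 0.303. The fit was tested on simulated data: with a known change planted, 35.8% of 2-fold, 83.6% of 4-fold and 93.9% of 8-fold changes were recovered in the L-DOPA contrast (22.4%, 77.6% and 92.4% for zonisamide, 34.3%, 71.6% and 81.8% for the lesion, 20.9%, 71.6% and 89.4% for both drugs), and 0 features were called when none was changed. In the runs with planted changes, 5 unchanged features were also called for L-DOPA and 6 in each other contrast. The simulated noise was independent between genes, without effects shared by an array or slide. These values therefore do not show how many false calls such shared effects give in the real arrays.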

Results

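RNA from the striatum of male Wistar rats was measured on 12 Agilent single-colour arrays. Each rat had been injected with 6-hydroxydopamine, a toxin taken up by dopamine neurons, into the left medial forebrain bundle, the tract that carries dopamine fibres to the striatum. Rats that turned at least 7 times per minute after 3 mg/kg methamphetamine entered the study. There were 4 groups of 3 arrays: the non-lesioned striatum after saline, the lesioned striatum after saline, the lesioned striatum after L-DOPA at 100 mg/kg, and the lesioned striatum after L-DOPA at 100 mg/kg with zonisamide at 50 mg/kg. L-DOPA is the precursor of dopamine, and zonisamide is an antiepileptic drug also used in Parkinson's disease. Treatment was daily for 7 days, with zonisamide given 30 min after L-DOPA.

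The 75th percentile of the signal lay between 793 intensity units (L-DOPA with zonisamide, replicate 3) and 1737 (L-DOPA with zonisamide, replicate 2). Between 67.6% and 74.0% of probes were well above background, and correlations between arrays ran from 0.935 to 0.984. Per the file headers, the overall quality result of the extraction was in range on replicate 3 of lesioned saline and on no other array. The spread of replicate spots of a probe differed widely, from 3.74% on replicate 3 of lesioned saline to 27.8% on replicate 3 of L-DOPA with zonisamide. It was over 20% on the 3 non-lesioned arrays and on replicate 3 of both drug groups. The number of arrays, 3 per group, limits the precision of every value below. After filtering, 19412 features were tested, of which 11110 carried a gene symbol. Chromosome positions are not given here. Values are log2 signals relative to each array's 75th percentile.

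Markers of the choroid plexus, the tissue of the ventricle wall that makes cerebrospinal fluid, differed strongly between arrays of the same group. Transthyretin (Ttr), its most abundant transcript, stood at 6.73 on replicate 3 of the non-lesioned side, against 2.32 and 3.05 on the others. In lesioned saline Ttr was -0.74, 4.35 and 3.30. With L-DOPA it was 4.31, 7.27 and 6.89, and with L-DOPA and zonisamide 4.28, 2.72 and 6.67. Each comparison below uses at least 1 of the 4 arrays with the highest levels: 1 of the non-lesioned side, 2 of L-DOPA and 1 of L-DOPA with zonisamide.

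The lesioned side after saline was compared with the non-lesioned side, which asks what dopamine loss did to striatal RNA. No single feature passed at an adjusted p under 0.05 with limma, while 1646 had an unadjusted p under 0.05 against 971 by chance. Genes of the direct-pathway spiny neuron, the striatal output cell that carries the D1 dopamine receptor, were lower as a group. All 8 tested members were lower, with a median log2 change of -0.49 (adjusted p = 2.00e-05 by camera; adjusted p = 0.301 with an estimated correlation). None passed over all genes, and 4 fell when adjusted over the list alone. These were Isl1, a transcription factor of this cell type (-0.51 ± 0.15, SE), Ebf1 (-0.50 ± 0.16), and the neuropeptide precursors Pdyn (-0.68 ± 0.22) and Tac1 (-0.66 ± 0.24). Within the only slide that held both groups, the median of this list was -0.43.

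Other genes fixed for every comparison did not pass on the lesioned side. Penk, the enkephalin precursor of indirect-pathway neurons, had a log2 change of 0.69 ± 0.21 (SE, adjusted p = 0.502). Drd1 and Drd2, the dopamine D1 and D2 receptors, had values of -0.44 ± 0.20 and 0.15 ± 0.21. Th, which encodes the rate-limiting enzyme of dopamine synthesis, had a value of 1.37 ± 0.31 (adjusted p = 0.305). The 10 named genes with the smallest p, none of which passed, were all higher on the lesioned side. They were Igsf7 l1 (2.04 ± 0.24, adjusted p = 0.129), the activin-binding protein Fst (1.70 ± 0.24), Bpifb1 (1.55 ± 0.23), the complement inhibitor Serping1 (1.91 ± 0.28), Vom2r15 (4.93 ± 0.74, above background on 1 of 3 non-lesioned arrays), Spmap2 (1.30 ± 0.20), the glutamate receptor scaffold Grip2 (1.48 ± 0.25), Slc10a5 (1.58 ± 0.27), Btnl5 (at least 10.2-fold higher) and Upb1 (1.60 ± 0.28).

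Vascular cell genes were higher as a group after the lesion, with 16 of 18 members higher and a median of 0.41 (adjusted p = 0.0236; adjusted p = 0.700 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Examples were Rgs5 of pericytes (0.58 ± 0.20), smooth-muscle actin Acta2 (0.51 ± 0.21) and the endothelial receptor Tek (0.54 ± 0.25). Choroid plexus genes were lower in 11 of 12 members, with a median of -1.58 (adjusted p = 0.0347; adjusted p = 0.807 with an estimated correlation), no member passing over all genes or adjusted over the list alone. Ttr changed by -1.73 ± 1.60 and Sostdc1 by -2.72 ± 2.46, each well within the spread of the arrays. Without replicate 3 of the non-lesioned side the adjusted p was 0.827 for the choroid plexus list, with the direction turned, and 0.269 for the vascular list. The choroid plexus list was also at 0.198 without replicate 1 of lesioned saline and at 0.0557 without its replicate 3; the vascular list was at 0.0852 without replicate 1 of the non-lesioned side and at 0.0557 without replicate 3 of lesioned saline. With slide as a fixed block the adjusted p was 0.689 (direction turned) for choroid plexus and 0.179 for vascular genes, and the choroid plexus list was at 0.220 with quantile normalization and 0.305 with normexp and quantile normalization. Within the slide that held both groups the vascular median was 0.34 and the choroid plexus median -0.34. Without replicate 3 of the non-lesioned side 13 features passed, 1 passed without its replicate 2, and without each of the other arrays none did (808 to 2324 at an unadjusted p under 0.05 with limma).

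L-DOPA was compared with saline on the lesioned side, which asks what a week of dopamine replacement did to the denervated striatum. It raised 64 features and lowered 20 with limma (adjusted p under 0.05, 19412 tested), and 43 of the 84 carried a gene symbol, 33 higher and 10 lower. Prodynorphin (Pdyn), the opioid peptide precursor of direct-pathway neurons, rose 3.37-fold (log2 1.75 ± 0.22, SE, n = 3 per group, adjusted p = 0.0151). Several of the largest rises were in genes not above background after saline. Cimap2 was at least 11.2-fold higher and the transcription factor Meox1 at least 8.58-fold higher (adjusted p = 0.00635 for both). The retinoid-induced receptor Gprc5a rose 16.4-fold (log2 4.03 ± 0.49; above background on 1 of 3 saline arrays) and the secreted signal Wnt10a also rose 16.4-fold (log2 4.03 ± 0.63).

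Further rises were in the lens crystallin Cryba2 (at least 14.0-fold), the metalloproteinase inhibitor Timp1 (9.24-fold, log2 3.21 ± 0.56, adjusted p = 0.0472) and the transcriptional repressor Prdm1 (at least 4.23-fold). The 8 largest falls were in Igsf7 l1 (-2.41 ± 0.24, adjusted p = 0.00635), the lactate transporter Slc16a1 (-1.86 ± 0.30), the transcription factors Klf2 (-1.62 ± 0.19) and Klf4 (-1.36 ± 0.16), Gdnf, a survival factor for dopamine neurons (-1.58 ± 0.27), Nat8f1 (-1.35 ± 0.18), Tspoap1 (-1.27 ± 0.22) and the synaptic vesicle protein Svop (-1.11 ± 0.19). Tac1 (0.32 ± 0.24), Drd1 (0.17 ± 0.20), Drd2 (-0.12 ± 0.21), Penk (-0.05 ± 0.21) and Th (-0.24 ± 0.31) did not pass. The groups did not overlap in any of the 84 features; over all features 22.4% showed no overlap, where chance gives 10%.

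**Figure D1:**
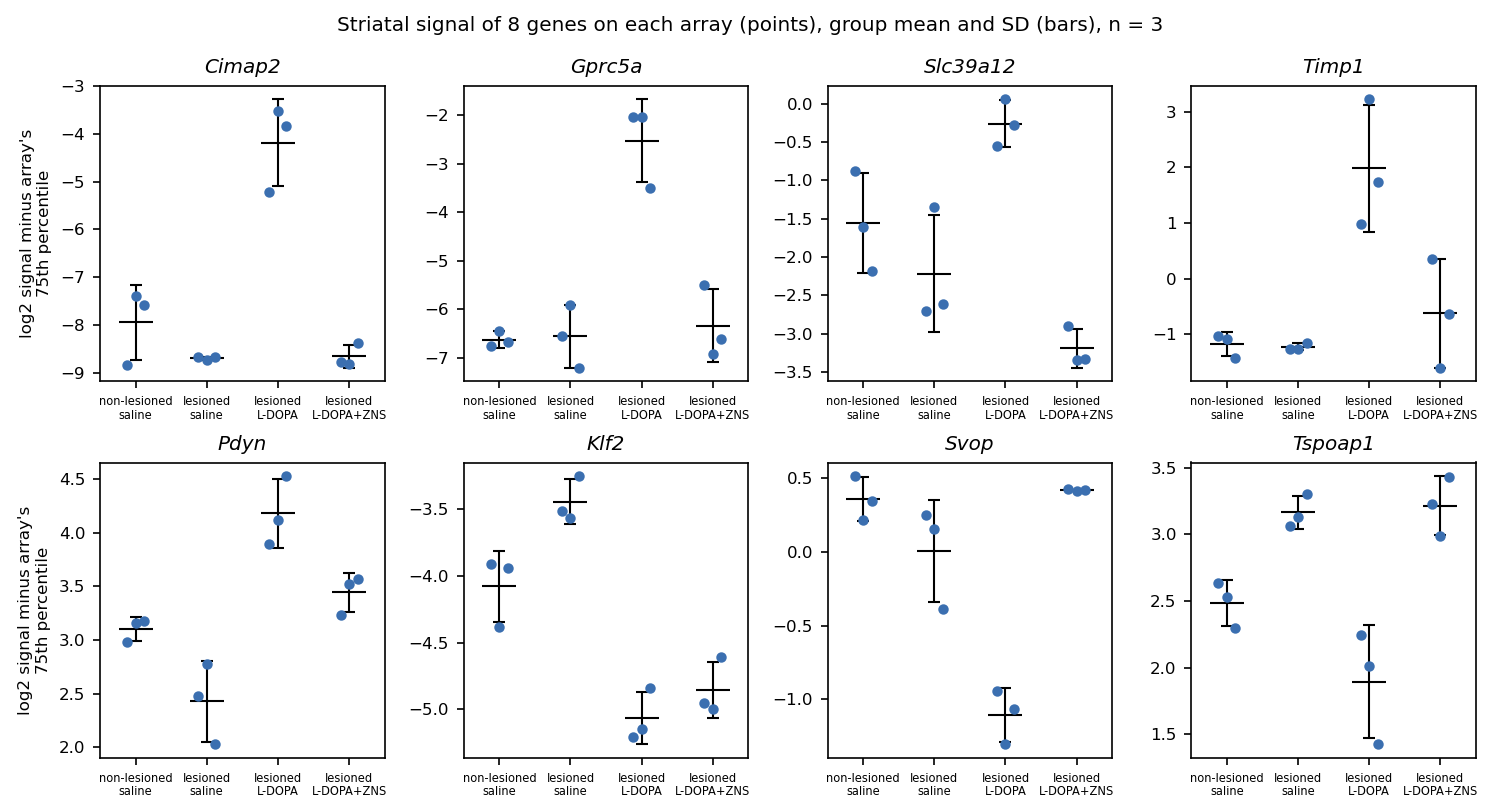
Signal of 8 genes on each of the 12 arrays (points), with the group mean and SD (bars, n = 3); the vertical axis is the log2 signal minus the array's 75th percentile, and ZNS stands for zonisamide. Cimap2 stood at a mean of -8.69 after saline and -4.19 after L-DOPA, and Pdyn at 2.43 and 4.18, on the lesioned side.

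Late activity-response genes, which follow sustained neuronal firing, were higher as a group with L-DOPA, in 14 of 19 members with a median of 0.49 (adjusted p = 0.000627; adjusted p = 0.195 with an estimated correlation). Of these none passed over all genes and 6 rose when adjusted over the list alone, among them the synaptic pentraxin Nptx1 (1.45 ± 0.29), the cAMP-responsive repressor Crem (1.07 ± 0.22) and the activin subunit Inhba (2.07 ± 0.42). Nptx1 is also in the cortical neuron list, whose medians within slides were 1.18 and -0.03. Neuropeptide genes were higher in 13 of 17 (median 0.19, adjusted p = 0.0181; adjusted p = 0.295 with an estimated correlation). Over all genes 1 rose, Pdyn, and 2 rose adjusted over the list alone, Pdyn and Trh (2.88 ± 0.70), while Tac3 (0.86 ± 0.33) and neurotensin Nts (0.67 ± 0.27) did not pass. Genes of endoplasmic reticulum stress and heat shock were higher in 12 of 16 (median 0.13, adjusted p = 0.0238; adjusted p = 0.295 with an estimated correlation). None of these passed over all genes; adjusted over the list alone 3 rose, Creld2 (0.65 ± 0.15), Ddit3 (0.55 ± 0.16) and Hspb1 (1.29 ± 0.40), and Pdia4 fell (-1.46 ± 0.41).

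Spiny neuron genes shared by both output pathways were lower in 9 of 13 members after L-DOPA (median -0.40, adjusted p = 0.0183; adjusted p = 0.404 with an estimated correlation). Not one passed over all genes and 2 fell adjusted over the list alone, among them the phosphodiesterase Pde1b (-0.86 ± 0.24). Interneuron genes were lower in 10 of 12 (median -0.42, adjusted p = 0.0192; adjusted p = 0.353 with an estimated correlation), none passing over all genes or adjusted over the list alone; somatostatin Sst had a value of -1.67 ± 0.71 and Lhx6 of -0.40 ± 0.17. Immediate-early genes were not called as a group (adjusted p = 0.179, test downward), with a median near 0 and a mean of -0.20. Of their 24 members Klf2 and Klf4 fell and 22 did not pass, and adjusted over the list alone 3 rose and 5 fell. The growth-arrest gene Gadd45b in this list had a value of 0.81 ± 0.21.

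Markers of some non-neuronal cells also moved with L-DOPA, while those of microglia and MHC (median -0.03, adjusted p = 0.775), the oligodendrocyte lineage (0.08, adjusted p = 0.326) and the meninges (0.27, adjusted p = 0.326) were not called. Astrocyte genes were higher in 11 of 16 (median 0.30, adjusted p = 0.0183, adjusted p = 0.376 with an estimated correlation). Over all genes 1 rose, Timp1, and adjusted over the list alone 5 rose, including lipocalin Lcn2 (2.95 ± 0.56) and the chemokine Cxcl10 (1.53 ± 0.43), while 1 fell, Aldoc (-0.70 ± 0.21). A further tested probe of Aldoc was at -0.18. Vascular genes were higher in 12 of 18 (median 0.28, adjusted p = 0.0192; adjusted p = 0.505 with an estimated correlation). None passed over all genes and 3 rose adjusted over the list alone: the receptor Kdr (1.30 ± 0.29), Angpt2 (2.20 ± 0.55) and Nes (0.92 ± 0.23). The 5 blood cell genes were all higher (median 0.66, adjusted p = 0.0215; adjusted p = 0.295 with an estimated correlation), and no member passed over all genes or adjusted over the list alone; beta-globin Hbb had a value of 0.33 ± 0.37. Choroid plexus genes were higher in 10 of 12 with a median of 2.53 (adjusted p = 0.0176; adjusted p = 0.567 with an estimated correlation). Among them Ttr (3.85 ± 1.60), Sostdc1 (5.02 ± 2.46) and Kl (3.98 ± 2.01) did not pass over all genes or adjusted over the list alone.

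The number of features called for L-DOPA depended on single arrays. It was 210 without replicate 1 of L-DOPA, 8 without its replicate 2 and 10 without its replicate 3, and 2, 9 and 25 without replicates 1, 2 and 3 of lesioned saline. All 84 kept their direction in each of these fits, as they had to, because the groups did not overlap in any of them. With slide as a fixed block none passed (1649 at an unadjusted p under 0.05 with limma). Within the slides that held both groups the medians were 1.38 and 1.75 for the 64 higher features and -1.37 and -1.56 for the 20 lower features. The groups did not overlap in any of these features, so their directions within slides were fixed in advance and are no check on the slides. Normexp background correction with quantile normalization left 30 features, 27 higher and 3 lower.

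The list results for L-DOPA depended on arrays too, except that late activity-response genes kept their call without any single array. Without replicate 1 of lesioned saline the adjusted p was 0.0528 for the astrocyte, vascular, choroid plexus and shared spiny neuron lists, 0.0595 for stress genes and 0.0707 for interneuron genes. Without its replicate 2 it was 0.0822 for blood cell and 0.0672 for vascular genes, and without its replicate 3 it was 0.0704 for neuropeptide and stress genes. Without replicate 2 of L-DOPA it was 0.0638 for astrocyte, 0.0942 for shared spiny neuron, 0.115 for choroid plexus and 0.109 for blood cell, vascular, interneuron and stress genes, and without its replicate 1 it was 0.0575 for stress genes. Within slides the blood cell median was -0.21 on the first and 1.33 on the second, and the neuropeptide median 0.23 and -0.02; the medians of the other called lists kept their direction on both slides. With slide as a fixed block the adjusted p was 0.0776 for blood cell and shared spiny neuron genes and 0.127 for neuropeptide genes. With normexp and quantile normalization it was 0.194 for stress and 0.0635 for interneuron genes, and without the 5 arrays of high replicate-spot spread 0.0505 for astrocyte and vascular genes and 0.0688 for neuropeptide genes.

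L-DOPA with zonisamide was then compared with L-DOPA alone, the contrast in the title of the study. Zonisamide lowered 76 features and raised 17 with limma (adjusted p under 0.05), and 55 of the 93 carried a gene symbol, 48 lower and 7 higher. Several of the genes with the largest L-DOPA rises were lower again. Cimap2 was at least 12.9-fold lower and Meox1 at least 9.89-fold lower (adjusted p = 0.0102 for both), and neither was above background on any zonisamide array. Gprc5a fell by 3.82 ± 0.49 on the log2 scale (SE, n = 3 per group, adjusted p = 0.0177) and Cryba2 by 3.35 ± 0.56, while Prdm1 was at least 4.58-fold lower. The succinate receptor Sucnr1 was at least 6.28-fold lower and the zinc transporter Slc39a12 changed by -2.94 ± 0.41 (adjusted p = 0.0240).

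The 7 named genes that rose with zonisamide were Svop (1.52 ± 0.19, adjusted p = 0.0177), Serhl2 (1.45 ± 0.24), Tspoap1 (1.32 ± 0.22), C8h11orf87 (1.25 ± 0.19), Nat8f1 (1.24 ± 0.18), the signalling scaffold Cnksr1 (1.18 ± 0.21) and Spmip8 (1.09 ± 0.18). Svop, Tspoap1 and Nat8f1 were among those that fell with L-DOPA alone. Other genes named for L-DOPA did not pass: Wnt10a (-3.10 ± 0.63, adjusted p = 0.0680), Timp1 (-2.61 ± 0.56, adjusted p = 0.0803), Slc16a1 (1.47 ± 0.30, adjusted p = 0.0664), Gdnf (1.21 ± 0.27, adjusted p = 0.0849), Igsf7 l1 (0.90 ± 0.24), Klf2 (0.21 ± 0.19) and Klf4 (0.07 ± 0.16). Nor did Pdyn (-0.74 ± 0.22, adjusted p = 0.199), Penk (-0.63 ± 0.21), Tac1 (0.42 ± 0.24), Th (-0.41 ± 0.31), Drd2 (-0.09 ± 0.21) or Drd1 (-0.07 ± 0.20). The groups did not overlap in any of the 93 features; over all features 17.3% showed no overlap, where chance gives 10%.

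Activity-regulated genes were lower when zonisamide was added. Of 24 immediate-early genes, the first to respond to neuronal firing, 19 were lower, with a median of -0.51 (adjusted p = 0.00147; adjusted p = 0.181 with an estimated correlation). Over all genes 1 fell, Gadd45b (-1.39 ± 0.21), and 5 fell adjusted over the list alone, including the kinase Sik1 (-1.26 ± 0.24), Maff (-1.57 ± 0.37) and Ier2 (-0.69 ± 0.17). The immediate-early median was -0.19 with normexp and quantile normalization. Late activity-response genes were lower in 15 of 19 (median -0.45, adjusted p = 0.000562; adjusted p = 0.181 with an estimated correlation). Nptx1 fell over all genes (-1.76 ± 0.29), and 5 fell adjusted over the list alone, with Crem at -1.20 ± 0.22 and Inhba at -1.94 ± 0.42. The cortical neuron list, which also holds Nptx1, had medians within slides of -0.87, -0.31 and 0.26. Genes reported for L-DOPA-induced dyskinesia, the involuntary movements of long treatment, were lower in 11 of 14 (median -0.54, adjusted p = 0.0299; adjusted p = 0.181 with an estimated correlation). Over all genes none passed. Adjusted over the list alone 7 fell and 1 rose, the falls including Pdyn, the serotonin receptor Htr1b (-0.88 ± 0.29), Trh (-2.03 ± 0.70) and Arc (-0.76 ± 0.27). Against lesioned saline the dyskinesia list was not called, with a median of -0.005 for L-DOPA alone and -0.29 for both drugs.

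Vascular genes were lower with zonisamide in 15 of 18 members, with a median of -0.66 (adjusted p = 4.98e-06; adjusted p = 0.210 with an estimated correlation). Of these none passed over all genes and 7 fell adjusted over the list alone, among them Nes (-1.24 ± 0.23), the tight-junction gene Cldn5 (-0.92 ± 0.19), Kdr (-1.45 ± 0.29) and Pecam1 (-0.93 ± 0.19). The 5 blood cell genes were lower (median -1.18, adjusted p = 0.00451; adjusted p = 0.181 with an estimated correlation), none passing over all genes and 3 falling adjusted over the list alone, with Hbb at -1.18 ± 0.37 and Camp at -1.28 ± 0.42. Microglia and MHC genes were lower in 16 of 20 (median -0.47, adjusted p = 0.00616; adjusted p = 0.286 with an estimated correlation). None passed over all genes and 1 fell adjusted over the list alone, Ly86 (-0.72 ± 0.15), with Itgam at -2.10 ± 0.68 and Tmem119 at 0.63 ± 0.19. Choroid plexus genes, with a median of -1.46, were not called (adjusted p = 0.251). They were called without replicate 1 of L-DOPA (0.0424), without replicate 3 of L-DOPA with zonisamide (0.0236) and without the 5 arrays of high spread (0.00923), and their medians within slides were -0.02, -4.62 and 0.23.

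**Figure D2:**
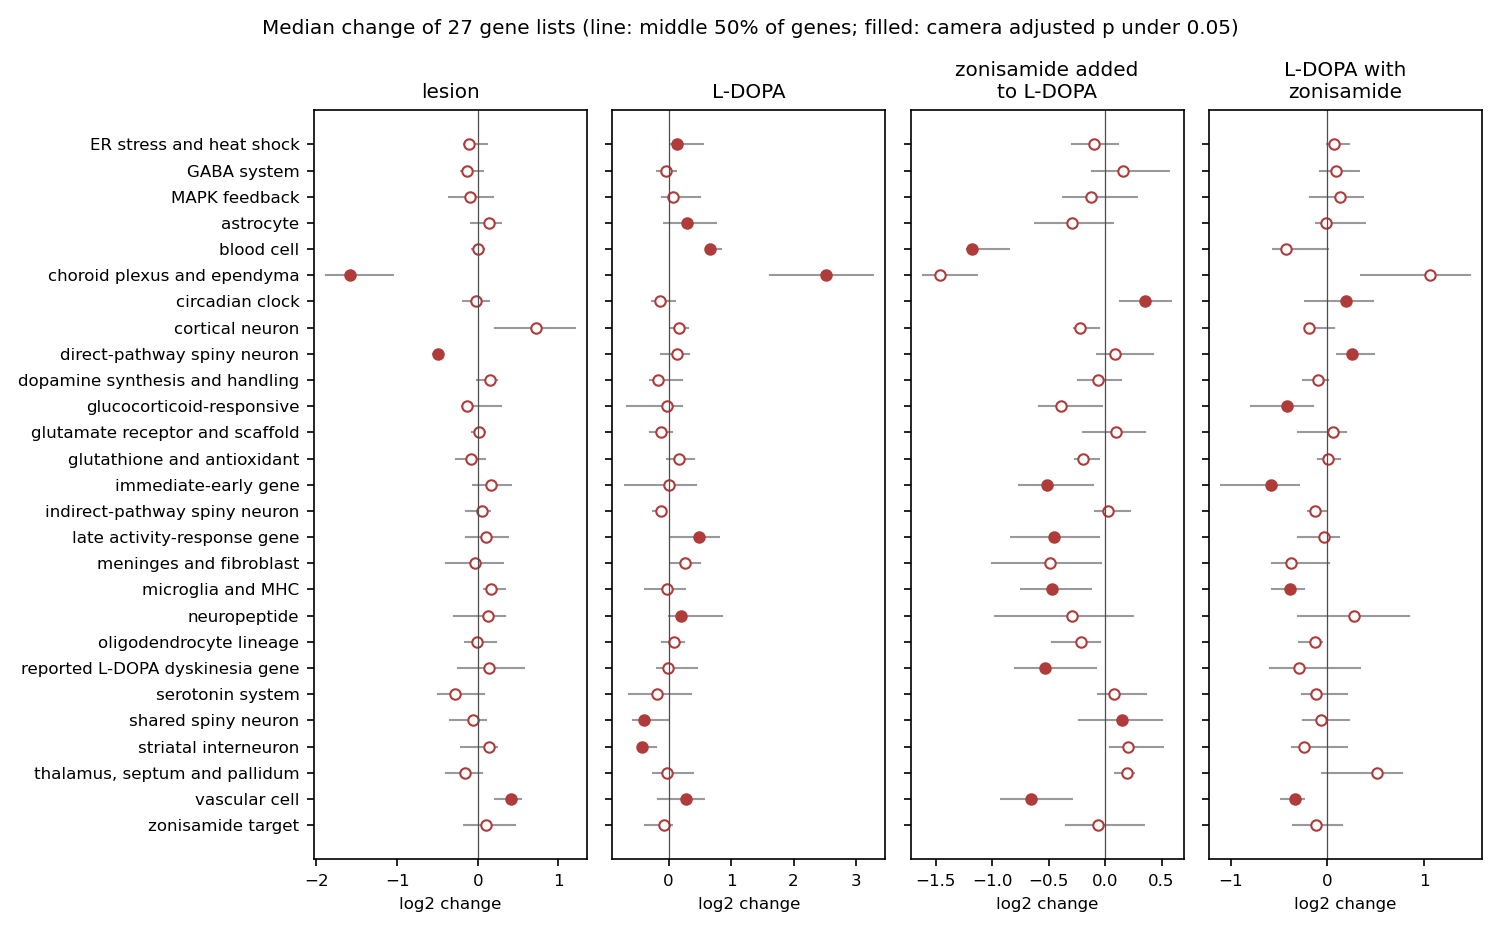
Median log2 change of 27 gene lists in the 4 comparisons (points), with the middle 50% of each list's genes (lines); filled points had a camera adjusted p under 0.05. The immediate-early list stood at -0.51 when zonisamide was added and at -0.58 for both drugs against saline, both filled.

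Clock genes were higher with zonisamide in 11 of 14 (median 0.35, adjusted p = 0.0113; adjusted p = 0.196 with an estimated correlation), none passing over all genes or adjusted over the list alone. Dbp (0.60 ± 0.18), Nr1d1 (0.55 ± 0.17) and Tef (0.49 ± 0.20) were among them, while Clock had a value of -0.40 ± 0.16. Shared spiny neuron genes were higher as a group in camera, with 7 of 13 members higher and a median of 0.15 (adjusted p = 0.0479; adjusted p = 0.410 with an estimated correlation). No member passed over all genes and 3 rose adjusted over the list alone, among them Pde1b (1.12 ± 0.24) and Tmem158 (0.95 ± 0.26). With the replicate number as a block the adjusted p of this list was 0.0701; its medians within slides were -0.24, 0.62 and 0.40. The medians of the other called lists kept their direction on all 3 slides.

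With the replicate number as a block, 13 features passed for zonisamide, 3 higher and 10 lower, all among the 93. Of the 15 largest named changes, Svop, Cimap2, Meox1 and Gprc5a passed with the block and the other 11 had adjusted p values between 0.0547 and 0.0938. Of the list members called above, Nptx1 was at 0.0657 and Gadd45b at 0.0770 with the block, so neither passed. With slide as a fixed block none passed (2743 at an unadjusted p under 0.05 with limma). On the 3 slides the medians were -1.27, -1.86 and -1.76 for the 76 lower features and 1.23, 1.59 and 1.66 for the 17 higher features. As the groups did not overlap in any of these features, their directions within slides were fixed in advance and are no check on the slides. The count was 253 without replicate 1 of L-DOPA, 6 without its replicate 2 and 5 without its replicate 3, and 71, 0 and 22 without replicates 1, 2 and 3 of L-DOPA with zonisamide (2151 at an unadjusted p under 0.05 with limma where none passed). Without replicate 2 of that group the clock list was at an adjusted p of 0.102 and the shared spiny neuron list at 0.164. The latter was at 0.0801 without replicate 3 of that group, 0.112 without replicate 2 of L-DOPA and 0.0680 without replicate 3 of L-DOPA. The dyskinesia list was at 0.0798 without replicate 3 of L-DOPA and at 0.0804 and 0.0568 without replicates 1 and 3 of L-DOPA with zonisamide. Without the 5 arrays of high spread it was at 0.194 and the shared spiny neuron list at 0.220; the latter was at 0.132 with slide as a fixed block and at 0.0727 with quantile normalization.

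Both drugs together were compared with saline on the lesioned side. No single feature passed at an adjusted p under 0.05 with limma, while 1424 had an unadjusted p under 0.05 against 971 by chance. Immediate-early genes were lower as a group in 23 of 24 members, with a median of -0.58 (adjusted p = 3.08e-10; adjusted p = 0.0334 with an estimated correlation, so that this call held). It was the only list call in the 4 comparisons to do so. None of its members passed over all genes and 7 fell adjusted over the list alone, including Klf4 (-1.28 ± 0.16), Klf2 (-1.41 ± 0.19), Fosl2 (-1.12 ± 0.19) and the orphan nuclear receptor Nr4a1 (-1.32 ± 0.29). A further tested probe of Fosl2 was at -0.43. The median of the immediate-early list was -0.62 and -0.52 within the slides that held both groups. Over all arrays it was -0.24 with normexp and quantile normalization. Microglia and MHC genes were lower in all 20 (median -0.39, adjusted p = 0.000115, adjusted p = 0.256 with an estimated correlation), none passing over all genes or adjusted over the list alone, with Ly86 at -0.45 ± 0.15, Csf1r at -0.95 ± 0.34 and Tyrobp at -0.80 ± 0.31. A further tested probe of Csf1r was at -0.13.

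Direct-pathway spiny neuron genes were higher in all 8 (median 0.26, adjusted p = 0.00175; adjusted p = 0.256 with an estimated correlation). Over all genes none passed and 2 rose adjusted over the list alone, Pdyn (1.01 ± 0.22) and Tac1 (0.74 ± 0.24). Vascular genes were lower in all 18 (median -0.33, adjusted p = 0.00342; adjusted p = 0.484 with an estimated correlation), none passing over all genes or adjusted over the list alone; Cldn5 was at -0.67 ± 0.19 and Rgs5 at -0.56 ± 0.20. Glucocorticoid-responsive genes were lower in 11 of 14 (median -0.41, adjusted p = 0.00639; adjusted p = 0.256 with an estimated correlation), with none passing over all genes and 5 falling adjusted over the list alone, such as Ddit4 (-0.81 ± 0.20) and Sgk1 (-0.93 ± 0.26). Clock genes were higher in 8 of 14 (median 0.19, adjusted p = 0.00892; adjusted p = 0.256 with an estimated correlation). None passed over all genes and 1 rose adjusted over the list alone, Bhlhe40 (1.17 ± 0.21), with Nr1d1 at 0.56 ± 0.17 and Per2 at 0.61 ± 0.23.

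Of the genes named in each comparison, the smallest p values for both drugs against saline also included Tnni2 (-1.21 ± 0.19), Fst (-1.53 ± 0.24), Igsf7 l1 (-1.51 ± 0.24), Spmip8 (1.07 ± 0.18), Tmem243 (-0.82 ± 0.15) and Sntg2 (0.88 ± 0.17), none of which passed. Penk (-0.67 ± 0.21), Th (-0.64 ± 0.31), Drd2 (-0.20 ± 0.21) and Drd1 (0.10 ± 0.20) did not pass either. Without replicate 2 of L-DOPA with zonisamide the adjusted p was 0.108 for direct-pathway, 0.115 for vascular and 0.131 for clock genes, and glucocorticoid-responsive genes were at 0.0585 without replicate 2 of lesioned saline and at 0.0827 without replicate 1 of L-DOPA with zonisamide. The glucocorticoid list was also at 0.0725 with slide as a fixed block and at 0.0842 without the arrays of high spread, and the direct-pathway list at 0.0512 with normexp and quantile normalization. With that scaling the glucocorticoid median shrank to -0.06, from -0.41. Within slides the medians of all 6 called lists kept their direction. The count of features was 1 without replicate 3 of lesioned saline, 3 without replicate 1 of L-DOPA with zonisamide, and 0 without each of the others (949 to 1676 at an unadjusted p under 0.05 with limma).

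The size of the L-DOPA response with and without zonisamide was compared over the 84 features called for L-DOPA. The change from saline was smaller with zonisamide in 83 of them. The 64 higher features had a median change of 1.74 with L-DOPA alone and 0.26 with zonisamide added, and the 20 lower features -1.60 and -0.32. The median ratio of the 2 changes was 0.18. Because the features were chosen on the L-DOPA arrays, a ratio below 1 arises by selection alone; in 100 simulations with the same true change in both groups its median was 0.828 (95% range 0.593 to 1.05), and none lay at or below the observed value. With no true change in either group the simulated median was 0.551 (-0.44 to 1.37), and 15 of 100 lay at or below it. Both lists of calls shared 39 features, 30 higher with L-DOPA and lower with zonisamide and 9 the other way. This overlap comes from the fit without the replicate number as a block. With the block only 13 features passed for zonisamide, so no more than these could be shared. Independent lists would share 0.251 and 0.0175. Simulated unchanged groups sharing the L-DOPA arrays gave 0. Groups without change yield few or no calls to share, so this simulation cannot show how much the shared arrays add to the overlap. The groups of 3 cannot be split to keep 2 arrays in each part, so part of the excess may come from the shared arrays.

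**Figure D3:**
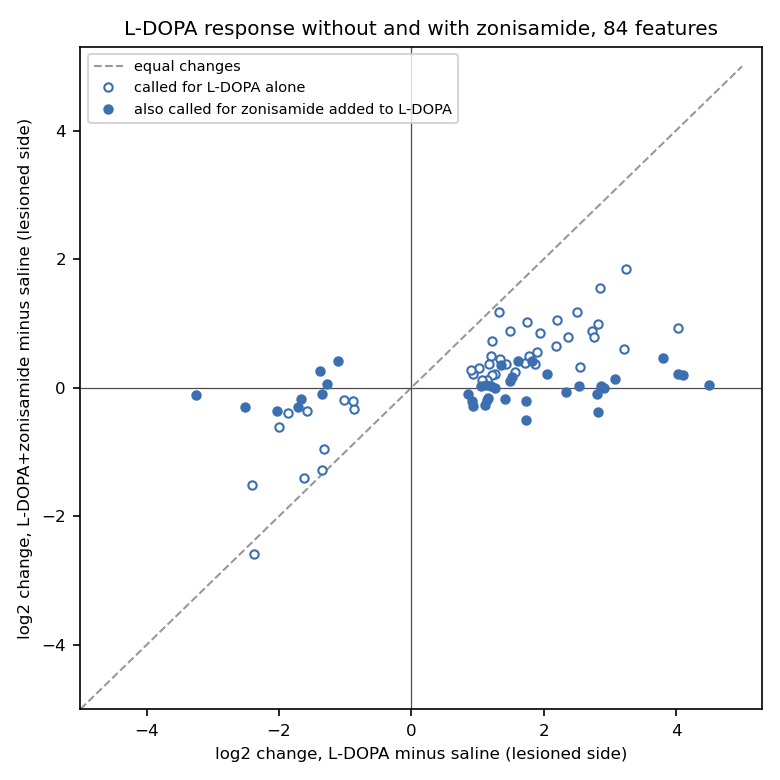
Log2 change from lesioned saline with L-DOPA alone (horizontal axis) and with L-DOPA and zonisamide (vertical axis) for the 84 features called for L-DOPA; filled points were also called for zonisamide added to L-DOPA, and the dashed line marks equal changes. The change with zonisamide was the smaller in 83 of the 84.

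Across the 19412 features, the change with the lesion and the change with L-DOPA had a correlation of -0.50. Both use the lesioned saline arrays, with opposite sign, and simulated unchanged groups gave a mean of -0.48 (-0.80 to -0.07). The covariance was -0.16 against a simulated -0.11 (-0.22 to -0.01). For L-DOPA and zonisamide, which share the L-DOPA arrays, the correlation was -0.58 against a simulated -0.50 (-0.79 to -0.10) and the covariance -0.18 against -0.11 (-0.22 to -0.02). Each observed value lay inside the simulated range. Features are not independent replicates, and no feature was called for the lesion.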

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

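Slide as a random block, Ttr as a covariate and leaving out the 5 arrays with a replicate-spot spread over 20% were tests chosen after the results were seen. The 84 features called for L-DOPA and the 93 for zonisamide kept their direction in every alternative that measured them. The groups did not overlap in any of them, so fits of the same values with fewer or reweighted arrays could not turn the direction. The kept direction is therefore no sign of stability, and the counts were not stable. For L-DOPA the count was 30 with normexp and quantile normalization together, 48 without a filter on dim probes, 446 with array weights, 34 with the replicate block (22 higher, 12 lower), and 1 without the 5 arrays. For zonisamide it was 8 with both, 45 without the filter, 13 with the replicate block, 188 with slide as a random block, 10 with Ttr as a covariate and 1 without the 5 arrays. Both counts were 0 when only the groups compared were fitted (2582 and 1962 at an unadjusted p under 0.05 with limma) and 0 with slide as a fixed block (1649 and 2743). With Ttr as a covariate the L-DOPA count was 0 (1163). Fewer arrays or residual degrees of freedom enter those fits; otherwise the cause was not tested. Quantile normalization gave 80 and 63, the stricter filter 81 and 84, mean probes 103 and 113, and the trend with a robust prior 79 and 75.

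Leaving out each array in turn gave 2 to 210 features for L-DOPA, 0 to 253 for zonisamide, 0 to 13 for the lesion and 0 to 3 for both drugs; the lone counts above 0 were the 1 and 13 and the 1 and 3 given above. The lesion and the combined treatment had 0 in every other alternative run for them, the replicate block included (1779 and 1525 at an unadjusted p under 0.05 with limma), and 0 with the block on saline arrays only (1240). The lesion could not be fitted without the 5 arrays, which include all 3 non-lesioned ones. The ratio of the L-DOPA response with zonisamide to that without was 0.18, rose to 0.26 with quantile normalization, was 0.21 with the replicate block, and ran from 0.12 to 0.23 without single arrays. The correlation of the lesion and L-DOPA changes was -0.50, -0.63 with normexp and quantile normalization, -0.50 with the replicate block, and -0.58 to -0.42 without single arrays; the cause was not tested. The choroid plexus list turned direction for the lesion without replicate 3 of the non-lesioned side (adjusted p = 0.827, from a low of 0.00151 without replicate 2) and with slide as a fixed block (0.689). The replicate block ended the list call of shared spiny neuron genes with zonisamide and brought the choroid plexus list for both drugs to an adjusted p of 0.0342, from 0.101; the other list calls stayed. Over all named genes and alternatives, 8155 values kept their direction and their side of the threshold. With the direction kept, 354 lost the threshold and 67 gained it. Another 101 turned direction without passing in either fit, and none turned that passed in either. The authors' combined table gave identical values and so no separate result. The normexp fits changed background correction, scaling and input (median spot brightness) at once, so their moves are not put down to normexp alone. Changes of genes near background are limited by signal: 17092 of 19412 features were well above it on all 12 arrays.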

Other observations

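The tests of MHC class I and interferon genes were written before their results were seen; the simulations of these lists and the tests of the other patterns in this part were chosen after the result was seen. Genes of antigen presentation by MHC class I were among the zonisamide calls and were picked from them; whether they were more than chance gives was not tested. RT1-A1 changed by -1.94 ± 0.29 (SE, adjusted p = 0.0255), RT1-CE2 by -2.73 ± 0.42, RT1-CE7 by -2.46 ± 0.38, RT1-S3 by -2.08 ± 0.34, RT1-CE11 by -2.05 ± 0.35 and RT1-CE5 by -1.62 ± 0.28. The peptide transporters Tap1 (-1.73 ± 0.30) and Tap2 (-1.39 ± 0.19) fell with them, as did the interferon-induced Ifitm3 (-1.31 ± 0.18) and Gbp2 (-1.53 ± 0.22). With the replicate number as a block none of these 10 genes passed, their adjusted p running from 0.0547 to 0.101. With L-DOPA, Tap2 (1.11 ± 0.19, adjusted p = 0.0458) and Ifitm3 (1.15 ± 0.18) had risen, and RT1-A1 was at 1.55 ± 0.29 (adjusted p = 0.0523).

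Tests were then made on 2 lists that hold no called gene. Interferon-response genes were higher with L-DOPA in 25 of 29 members (median 0.70, camera p = 5.54e-08; p = 0.0456 with an estimated correlation) and lower with zonisamide in 24 of 29 (median -0.76, p = 2.74e-07; p = 0.0557 with an estimated correlation). Isg20 was at 0.85 and -0.76, Oas1a at 1.27 and -1.41, and Irf1 at 0.57 and -0.56. Other genes of class I presentation were higher with L-DOPA in 20 of 24 (median 0.33, p = 2.67e-05; p = 0.0734 with an estimated correlation) and lower with zonisamide in 22 of 24 (median -0.54, p = 8.8e-07; p = 0.0424 with an estimated correlation). Adjusted over the 8 tests of both lists in the 4 comparisons, the adjusted p of these 4 results ran from 4.43e-07 to 5.34e-05, and was 0.147 for each with an estimated correlation, so none held there. With both drugs against saline, interferon genes were higher in 13 of 29 (median -0.02, adjusted p = 0.949) and class I genes in 8 of 24 (median -0.16, adjusted p = 0.181). For the lesion the medians were -0.15 (adjusted p = 0.181) and 0.09 (adjusted p = 0.949). With the preset correlation, each of the 4 results kept its direction and a camera p under 0.05 in 10 of 10 alternatives of scaling, block or a left-out array. The highest p was 0.00124, but the sizes varied. The estimated correlation, Ttr as a covariate and the fit without the arrays of high spread were not among these alternatives. The class I median for L-DOPA was 0.18 without replicate 2 of L-DOPA and 0.57 without its replicate 1, and for zonisamide -0.34 without that replicate 2; the interferon median with normexp and quantile normalization was 0.58 for L-DOPA and -0.45 for zonisamide. Both contrasts share the L-DOPA arrays with opposite sign, so opposite moves alone say little: in 1000 simulations of unchanged groups the interferon medians moved in opposite ways in 683 and the class I medians in 669. The simulated 95% range of the interferon median was -0.36 to 0.37 for L-DOPA and -0.35 to 0.41 for zonisamide, and that of class I -0.31 to 0.32 and -0.30 to 0.32; the observed medians lay outside these ranges, that of class I for L-DOPA barely. Within slides the interferon medians were 0.38 and 0.62 for L-DOPA and -0.23, -0.83 and -0.78 for zonisamide; the class I medians were 0.03 and 0.47, and -0.17, -0.88 and -0.61. The lists were also high on the non-lesioned array with high Ttr: the mean deviation of the interferon genes there was 0.344, against -0.391 and -0.284 on the others of its group (0.132 against -0.16 and -0.349 for class I). On the zonisamide array with high Ttr it was -0.209, against 0.0522 and -0.507, and -0.164 for class I, the highest of its group (-0.272 and -0.515). Of the 29 interferon genes 1 is also in another list, and none of the 24. An interferon response that rose with L-DOPA and was lower when zonisamide was added may be an explanation, but other cells were not excluded as the cause for these lists: choroid plexus tissue, and vascular and blood cells, whose markers moved the same way (medians 0.28 then -0.66, and 0.66 then -1.18). Microglia and MHC markers had a median of -0.03 with L-DOPA and of -0.47 when zonisamide was added, and of -0.39 for both drugs against saline. Close paralogs share sequence and outbred rats differ in class I alleles, and neither was tested.

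A first pattern is that features higher with L-DOPA were lower again with zonisamide. Choroid plexus tissue, high on 2 L-DOPA arrays, would raise such features also on the other 2 arrays with high Ttr. For 64 features chosen on the 2 groups alone (34 of them among the 64 called) the medians there were 0.342 (95% interval 0.11 to 0.503) and 0.229 (0.10 to 0.378) above the rest of their groups. Both lie below the 0.85 it would need. Each rests on 1 array, and the intervals resample features and leave out the spread between arrays. The test therefore cannot exclude choroid plexus tissue as the whole cause. With Ttr as a covariate the median change of the 64 called features went from 1.74 (median SE 0.249) to 1.49 (0.305), and the calls ended as the spread grew and the change shrank. As for more blood, the change of Hbb with L-DOPA had an upper 95% bound of 1.18, below the median rise of 1.74. That median is raised by selection, because the 64 features were called on the same L-DOPA arrays. Hbb is a single gene, so its value cannot exclude more blood as the whole cause. For the fall with zonisamide less blood cannot be told apart: Hbb was at -1.18 (lower bound -2.04) where these features had a median of -1.33, and the 5 blood cell genes went with the pattern (medians 0.66 and -1.18). A smaller share of spiny neurons would raise markers of other cells by about as much. The astrocyte, vascular, oligodendrocyte and microglia medians with L-DOPA were 0.302, 0.283, 0.0821 and -0.0304, all below the median rise of 1.74. The highest upper 95% bound was 0.746. The bounds resample genes and leave out the spread between arrays, so they cannot exclude it as the whole cause. When zonisamide was added the same lists were at -0.294, -0.658, -0.212 and -0.474, and shared spiny neuron genes at 0.15. The drugs themselves remain an open explanation.

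A further pattern is the lower level of immediate-early genes when zonisamide was added. Some members that vessels also express, such as Klf2, Klf4 and Gadd45b, were left out. The 17 others had a median of -0.516, 15 of them lower. Whether vessels also express these 17 was not tested, and the vascular list had a median of -0.66 in this comparison. A vascular part in the lower level can therefore not be excluded. The 95% interval of this median, taken over genes and not arrays, was -0.759 to -0.141. A difference in the time of day of tissue collection cannot be told apart. Clock genes that peak together changed by a mean of 0.33 (SE over genes 0.131) and the antiphase genes by 0.351 (SE over genes 0.376). This was too uncertain to show whether they moved in opposite ways. An effect of zonisamide on neuronal activity stays open and may be followed up.

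The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For L-DOPA the real split gave 84 features and the highest other 0; 1 of 10 splits was as large. For zonisamide these were 93 and 4, again 1 of 10, and among the splits that part all same-numbered pairs the highest other was 0. For the lesion the real split gave 0 and the highest other 1, and for both drugs 0 and 0, with 10 of 10 splits as large in each (1646 and 1424 at an unadjusted p under 0.05 with limma in the real splits). Counts at an unadjusted p under 0.05 in the other splits reached 1350 for the lesion and 1080 for both drugs. They reached 1528 for L-DOPA and 2011 for zonisamide, against 2192 and 2408 in the real splits.

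Replicate spots of a probe, divided into 2 sets, allow a check within arrays. Of the 84 L-DOPA features 47 had usable spots in both sets, and 46 of these showed at least 0.5 of the change in both sets. For zonisamide all 59 of 59 did. The features were called on the average of these same spots, so the selection favours agreement, and features not called were not examined this way. Spots of an array share its RNA, so the check says nothing about the spread between arrays. Features read from a single spot made up 41.7% of the L-DOPA calls, 35.5% of the zonisamide calls and 38.8% of the features tested; 2 L-DOPA calls and 1 zonisamide call had several spots but no usable spot in a set on some array.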
